A study of Mus musculus with 6 samples.

How the data were processed

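The series holds RNA-seq of sorted cells from mouse AGM at embryonic day 10.5: 3 libraries of GFP+ cells negative for CD206 and 3 of GFP+ cells positive for it. Per the labels' protocols, AGM were digested with collagenase for 45 min at 37 degrees Celsius, cells were sorted on GFP and on CD206 stained with APC, RNA was purified on micro columns, and libraries followed standard Illumina protocols. Strandedness, read length, trimming and sequencing batch are not given in the sources used here. Each deposited file holds raw whole-number read counts per gene for 1 library, which the authors made with featureCounts 1.5.2, per the file headers. Per the file headers, reads over exons were summed per gene of the GENCODE vM14 primary assembly annotation, with no option for strand, read pairs, multi-mapping reads or overlapping genes. Reads that map to several places or fall on overlapping genes are therefore not counted by this program's defaults, which lowers the counts of near-identical paralogs, and sense and antisense reads cannot be told apart. The submitters' processing notes name FastQC, STAR 2.3, featureCounts and Subread, and the builds mm10 and GRCm38.p5. The file headers name merged alignments, and what was merged is not given in the sources used here.

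Coordinates are those of the deposited files (GRCm38, 1-based). Symbols came from GENCODE release M21 by the gene identifier without its version, which matched 51633 of 51912 identifiers, and the 279 unmatched identifiers held between 0.010% and 0.014% of the reads. Groups were taken from the labels. The replicate number is the AGM number of the titles, and the series design names 3 independent litters, so libraries with the same number were read as 1 litter. Over the 12668 tested genes, deviations from the group means correlated across same-numbered libraries at 0.09, 0.04 and 0.18 for litters 1, 2 and 3. Xist had 0 reads in both libraries of litter 2 and 394 to 1931 in those of litters 1 and 3. No library was a copy of another: chi-square per degree of freedom within a group lay between 36.9 and 90.4 over genes with at least 20 reads in a pair. Total reads in genes ranged from 16730846 to 18214283, so that 3 reads stand for 0.16 to 0.18 CPM. Reads without molecular identifiers are not independent molecules: among genes with a mean of 20 to 50 reads in a group, 20.0% (CD206neg) and 23.6% (CD206pos) had 0 reads in at least 1 of 3 libraries. Intervals and floors therefore cover counting error only.

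Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood F test compared CD206pos with CD206neg without a litter block (robust estimation, Benjamini-Hochberg adjusted p under 0.05). The common biological coefficient of variation was 0.44. The standard error of a log2 fold change is its size divided by the square root of F. A fold is the ratio of mean scaled CPM. Where all libraries of a group had 0 reads, it is a lower bound against 3 counts over the group. Where a group had 1 to 3 reads in all, the ratio has an exact binomial 95% interval. The 30 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. Fry's directional test asks whether a list's genes move one way on balance and does not compare them with other genes. The lists overlap in some genes, such as Flt3, Dab2 and Mmp8.

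The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Mrc1, Csf1r, Ptprc, Adgre1, Cx3cr1 and Ccr2; the 10 largest changes in each direction among called genes with a symbol, at least 10 CPM in the higher group and the same direction in the 3 litters, without predicted and mitochondrial genes; up to 4 called members per list and direction with the smallest p; and Il1b, Tnf, Il6, Ccl2, Ccl3, Ccl4, Cxcl1, Cxcl2, Il10, Tgfb1, Lyve1, Timd4, Folr2 and Cd163. It gave 97 tested genes, 89 of them called, and some genes it takes are not reported here, nor is 1 gene first put among the macrophage reference genes of the closing section, which was left out for a reason other than its value, after the first result was seen, and the tests were run again without it. The alternatives were the litter block, RLE (DESeq2's size factors), upper-quartile and total scaling, a looser filter (at least 1 read) and a stricter filter (at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with sample quality weights, the fit without robust estimation, the removal of globin, mitochondrial and ribosomal protein genes, thinning to the smallest library total, and leaving out each library and each litter.

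The fits were tested on simulated data with 200 genes changed among the 12086 genes that passed the filter in the simulated libraries, drawn from the means, dispersions and depths of these 6 libraries. In the simulated CD206pos against CD206neg comparison, edgeR recovered 2% of genes changed 1.5-fold, 30% of those changed 2-fold, 68% of those changed 4-fold and 78% of those changed 8-fold, and 4.3% of its calls were false. DESeq2 recovered 6%, 46%, 72% and 80%, and 30.1% of its calls were false.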

Results

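RNA was sequenced from GFP-expressing cells of the mouse aorta-gonad-mesonephros (AGM), the region of the embryo around the dorsal aorta in which haematopoietic stem cells first appear, at day E10.5 of development. The embryos carried the MacGreen transgene, in which the Csf1r promoter drives EGFP, so that cells of the macrophage lineage and some of their precursors are green. GFP-positive cells were sorted by surface mannose receptor (CD206, the product of Mrc1) into a negative and a positive population, called CD206neg and CD206pos here. Each of 3 independent litters gave 1 library of each population, 6 libraries in all, and each library held cells from 3 to 5 AGM. The CD206neg libraries held 18214283, 16730846 and 16926014 reads assigned to genes (litters 1, 2 and 3) and the CD206pos libraries 16973143, 17868279 and 17918687. Between 16007 and 17745 of the 51912 listed genes had at least 1 read in a library. Values are given as CPM (reads of a gene relative to all reads in genes) scaled by TMM, with the mean ± SD of 3 libraries (n = 3), and a positive log2 fold change means a higher level in CD206pos.

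The first question was whether the sorted antigen separated the libraries as labelled. Mrc1 (ENSMUSG00000026712.3, GRCm38 chromosome 2, 14229392 to 14332057, plus strand) was at 51.6, 118.5 and 112 CPM in the CD206neg libraries of litters 1, 2 and 3 and at 1458, 1792 and 1506 CPM in the CD206pos libraries. This is a log2 fold change of 4.08 ± 0.32 (SE) with an adjusted p of 0.00084 (edgeR), and since cells were sorted on its product it checks the labels and is no finding. Without litter 2 the Mrc1 log2 fold change was 4.15 with an adjusted p of 0.075. Csf1r, the receptor whose promoter drives the reporter, was at 1600 ± 157 CPM in CD206neg and 2284 ± 615 CPM in CD206pos (adjusted p = 0.23), and among the alternatives run it passed the threshold only without CD206pos replicate 1 (adjusted p = 0.041). Ptprc, encoding the pan-leukocyte antigen CD45, was at 404 ± 127 and 489 ± 104 CPM (adjusted p = 0.66). The macrophage gene Adgre1, encoding F4/80, was 3.67-fold higher in CD206pos, at 690 ± 221 against 188 ± 40.0 CPM (adjusted p = 0.0071). The fractalkine receptor gene Cx3cr1 was at 1120 ± 205 CPM in CD206neg and 1830 ± 394 CPM in CD206pos, with an adjusted p of 0.093. The Cx3cr1 log2 fold change (0.71 ± 0.20, SE) passed with the litter as a block (adjusted p = 0.013) and also with DESeq2, limma-voom, the stricter filter or without CD206pos replicate 1 (adjusted p between 0.0097 and 0.048). Ccr2, the chemokine receptor of inflammatory monocytes, was 20.8-fold lower in CD206pos, at 1.40 ± 1.54 against 29.2 ± 14.3 CPM (adjusted p = 0.045). The Ccr2 call was lost with the litter block (adjusted p = 0.077), with limma-voom (adjusted p = 0.074) and without any one of CD206neg replicates 1, 2 and 3 or CD206pos replicate 2 (adjusted p between 0.11 and 0.18).

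**Figure D1:**
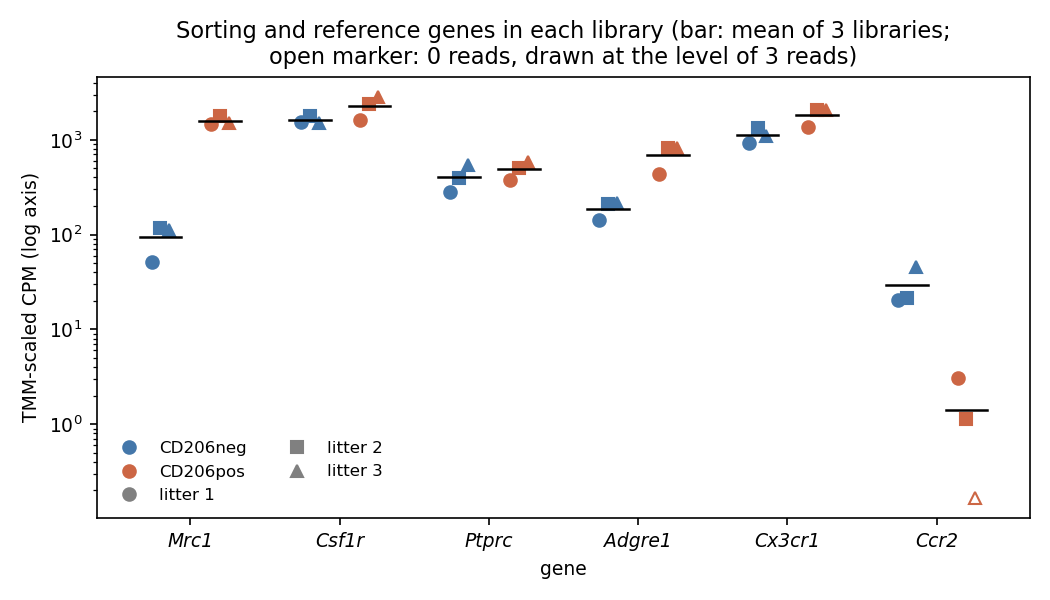
TMM-scaled CPM on a log axis for 6 genes in each of the 6 libraries, with colour for the population, marker shape for the litter and a bar for the mean of 3 libraries; an open marker stands for 0 reads and is drawn at the level of 3 reads. Mrc1 lies between 51.6 and 118.5 CPM in the CD206neg libraries and between 1458 and 1792 CPM in the CD206pos libraries.

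The main comparison asked which transcripts differ between CD206pos and CD206neg cells. CD206pos cells had higher levels of genes of resident, scavenging macrophages, among them Fcna, Lyve1, Pf4, Timd4 and Gas6, and of the chemokine genes Ccl2, Ccl7 and Ccl12. CD206neg cells had higher levels of some genes of blood progenitors, granulocytes and megakaryocytes, among them Kit, Mpo, S100a8 and Gfi1b. In the lists for these cells, 12 of 17 progenitor, 8 of 10 granule and 2 of 7 megakaryocyte genes tested were called. With an estimated correlation camera called none of these 3 lists (adjusted p = 0.056). Of 12668 genes tested, 617 changed in edgeR's quasi-likelihood test at an adjusted p under 0.05, with 376 higher and 241 lower in CD206pos. All 617 had the same direction in the 3 litters. With library totals as the only scaling, 273 genes were higher and 284 lower. The groups did not overlap for 3121 tested genes, 24.6% of them, where chance alone gives 10%. The number of calls fell, in most cases strongly, when a library or litter was left out. It was 190 without CD206neg replicate 2, 238 without CD206pos replicate 2 and 272 without CD206neg replicate 1. Without CD206neg replicate 3 it was 319, without CD206pos replicate 3 it was 355 and without CD206pos replicate 1 it was 561. Without both libraries of a litter, it was 307 (litter 1), 3 (litter 2: Kit, Pf4 and Gas6) and 153 (litter 3). Lower power with fewer libraries was not separated from the effect of those left out. Of the 89 called genes that the rule for named genes takes, 62 stayed called without litter 1, 3 without litter 2 and 46 without litter 3. DESeq2 called 1210 genes.

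Among called genes with at least 10 CPM in the higher group, the largest positive log2 fold changes belonged to the following 10, Mrc1 included. Fcna, encoding ficolin A, a lectin of the complement pathway, rose 59.2-fold, from 1.61 ± 1.56 to 95.5 ± 18.5 CPM. Lyve1, a hyaluronan receptor, rose 47.1-fold, from 2.78 ± 2.45 to 131 ± 35.5 CPM, and its call (adjusted p = 0.010) was lost without CD206neg replicate 2 (adjusted p = 0.075) and without CD206pos replicate 2 (adjusted p = 0.061). The chemokine genes Ccl7 and Ccl12 rose 23.4-fold and 14.0-fold. Pf4, which encodes a platelet chemokine that resident macrophages also express, was at 6.77 ± 1.53 CPM in CD206neg and 153 ± 4.93 CPM in CD206pos, a log2 fold change of 4.49 ± 0.23 (adjusted p = 0.00011). Timd4, a receptor for phosphatidylserine on dying cells, rose 20.3-fold, and Gas6, a ligand that bridges dying cells to TAM receptors (ENSMUSG00000031451.6, GRCm38 chromosome 8, 13465374 to 13494490, minus strand), rose 19.8-fold from 28.3 ± 5.13 to 560 ± 83.9 CPM (adjusted p = 0.00011). The syndecan gene Sdc4 and the leukotriene C4 synthase gene Ltc4s rose 14.3-fold and from 1.95 ± 0.38 to 21.5 ± 0.51 CPM.

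Among called genes with at least 10 CPM in the higher group, the 10 largest negative log2 fold changes belonged to genes without a read in any CD206pos library, so that each fold is a lower bound set by 3 counts over the group, and such bounds cover counting error only. Kit, the stem cell factor receptor, was at 82.7 ± 16.7 CPM in CD206neg, at least 1409-fold lower in CD206pos (adjusted p = 0.00042). S100a8, a granulocyte calcium-binding protein, was at 110 ± 75.2 CPM and at least 1866-fold lower. Its partner S100a9 was at 37.9 ± 35.0 CPM and at least 645-fold lower, a call lost without CD206pos replicate 2 (adjusted p = 0.053). Also among them were the organic cation transporter gene Slc22a3, the erythroid and megakaryocyte transcription factor gene Gfi1b, the granulocyte precursor gene Ms4a3, the neuregulin gene Nrg1 and the ficolin B gene Fcnb, at 12.4 to 28.4 CPM in CD206neg and at least 210-fold to 484-fold lower. With limma-voom the calls of S100a8, S100a9 and Ms4a3 were lost (adjusted p = 0.24, 0.25 and 0.10). In all, 56 of the lower genes had no read in any CD206pos library, and 4 of the higher genes had none in any CD206neg library.

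Genes of macrophage identity were examined in 3 lists fixed before the data were examined. Of 15 tested genes of CD206-high resident macrophages, 14 rose and 1 did not pass the test (median log2 fold change 2.83), and the same number rose when adjusted over the list alone. Besides Fcna, Lyve1, Pf4, Timd4, Gas6 and Ltc4s, this list holds the endocytic adaptor gene Dab2, which rose 6.25-fold from 673 ± 83.8 to 4206 ± 883 CPM, and the scavenger receptor gene Stab1, which rose 5.47-fold. The folate receptor gene Folr2 had 2 reads over the CD206neg libraries and 158 over the CD206pos libraries, a ratio of 81.7 with a 95% counting interval of 22.5 to 687. The Folr2 call (adjusted p = 0.046) was lost with the litter block (adjusted p = 0.071), with upper-quartile scaling, library totals or the looser filter (adjusted p = 0.051, 0.053 and 0.064) and without any one of the 6 libraries (adjusted p between 0.060 and 0.18). Cd163, a haemoglobin scavenger receptor, was below the filter with 1 and 17 reads in CD206pos replicates 2 and 3 and 0 in the other libraries. Of 18 macrophage and pan-myeloid genes 6 rose, Adgre1 among them, and 12 did not pass (median 0.63), against 11 higher and 3 lower when adjusted over the list alone. Of 15 microglia genes 3 rose and 12 did not pass (median 0.88), against 7 higher and 1 lower when adjusted over the list alone. Fcrls rose 7.66-fold and the purine receptor gene P2ry12 rose 3.11-fold. The camera test called all 3 lists higher (adjusted p = 1.1e-17, 0.0019 and 0.00080). With an estimated correlation the adjusted p values were 0.056, 0.43 and 0.41, and fry called only the first (adjusted p = 0.00022, 0.069 and 0.072).

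**Figure D2:**
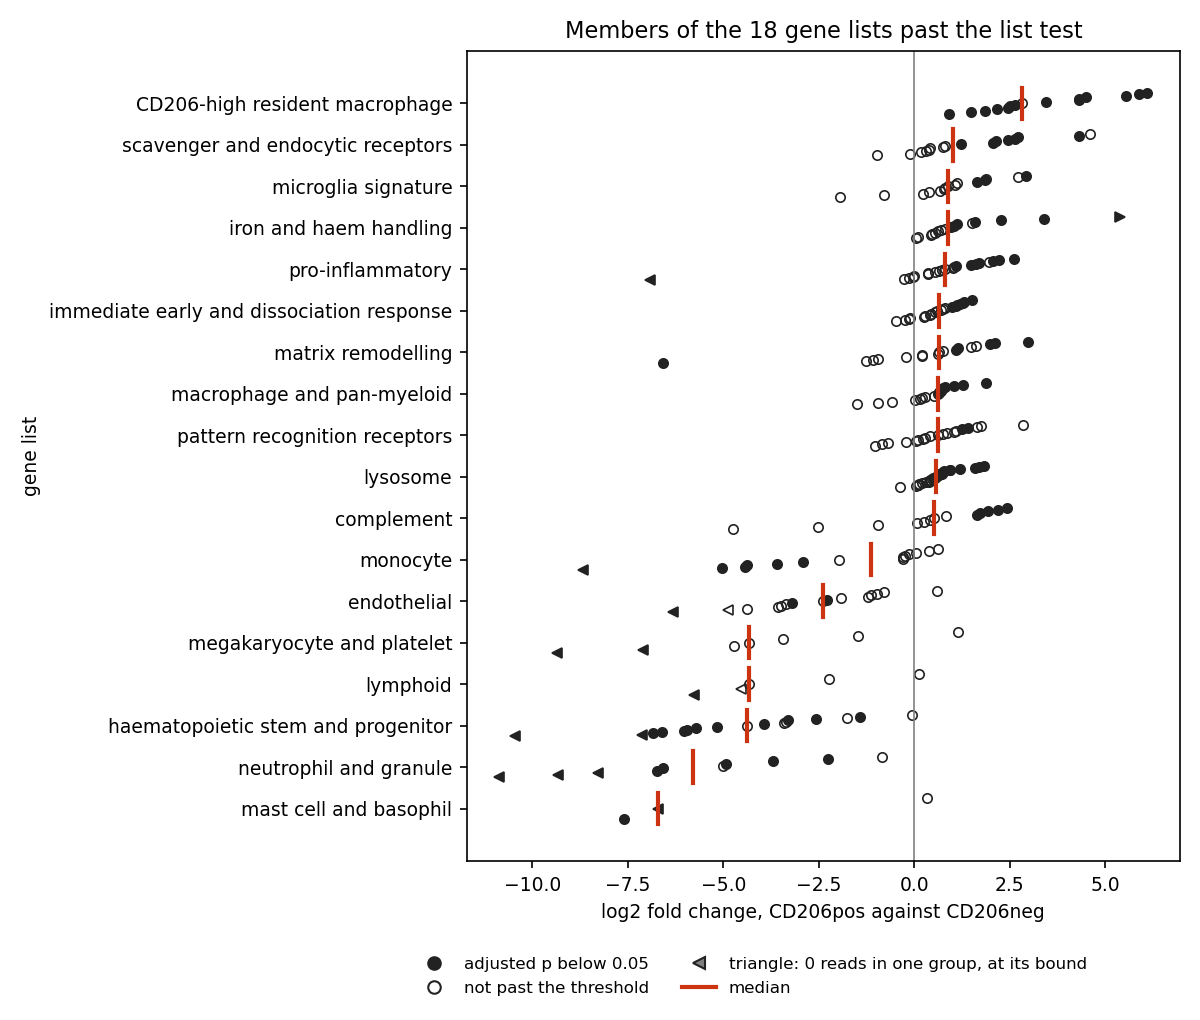
Log2 fold change of each tested member of the 18 gene lists past the list test, with filled symbols for members at an adjusted p under 0.05, triangles for genes without a read in one group, drawn at the bound set by 3 counts, and a bar at the median. Medians run from 2.83 for CD206-high resident macrophage genes to -6.71 for mast cell and basophil genes.

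Inflammatory genes were of interest because the series concerns pro-inflammatory macrophages of the AGM and the development of haematopoietic stem cells. Of 21 tested pro-inflammatory genes 7 rose in CD206pos, 1 fell and 13 did not pass the test (median 0.80), against 11 higher and 1 lower when adjusted over the list alone. The monocyte chemoattractant gene Ccl2 rose 6.16-fold, from 52.4 ± 15.2 to 323 ± 74.5 CPM (adjusted p = 0.0017). Tnf, encoding tumour necrosis factor, rose 3.25-fold, from 45.7 ± 11.7 to 149 ± 31.5 CPM (adjusted p = 0.0065). The Tnf log2 fold change of 1.70 was 1.48 without litter 1, 2.03 without litter 2 and 1.52 without litter 3, with adjusted p values of 0.074, 0.075 and 0.077. The costimulatory gene Cd86 rose 3.08-fold, and the chemokine gene Ccl4 rose 2.83-fold, from 276 ± 28.9 to 781 ± 264 CPM, a call lost without CD206neg replicate 2 (adjusted p = 0.068). Cxcl2 rose 4.16-fold from 5.46 ± 1.32 to 22.7 ± 10.2 CPM, a call lost with the litter block (adjusted p = 0.070), with limma-voom (adjusted p = 0.059) and without any one of CD206neg replicates 1, 2 and 3 or CD206pos replicates 1 and 3 (adjusted p between 0.085 and 0.12). The interleukin 12 subunit gene Il12a fell from 7.13 ± 4.81 CPM to 0 reads, at least 121-fold, a call lost with limma-voom (adjusted p = 0.12) and without CD206neg replicate 1, CD206neg replicate 2 or CD206pos replicate 2 (adjusted p between 0.058 and 0.10). Il1b was at 65.8 ± 16.8 and 83.8 ± 24.8 CPM (adjusted p = 0.59), Il6 at 1.28 ± 0.99 and 1.66 ± 0.56 CPM (adjusted p = 0.91), and Ccl3 at 354 ± 46.4 and 614 ± 216 CPM (adjusted p = 0.11, and 0.010 with DESeq2). Cxcl1 was below the filter, with 0, 6 and 0 reads in the CD206neg libraries and 37, 3 and 20 in the CD206pos libraries. The list was called higher by camera (adjusted p = 4.0e-05) and fry (adjusted p = 0.0041). With an estimated correlation its adjusted p was 0.056. The immediate early and dissociation response list was called higher as well, by camera (adjusted p = 4.0e-05) and fry (adjusted p = 0.0041).

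Of 15 genes of anti-inflammatory and alternative activation 2 rose and 13 did not pass (camera adjusted p = 0.21), against 3 higher and 3 lower when adjusted over the list alone. The genes that rose were the interleukin 4 receptor gene Il4ra, 2.21-fold, and the lipid scavenger gene Cd36, 4.41-fold. The Il4ra call was lost without CD206neg replicate 1 (adjusted p = 0.052) or CD206pos replicate 2 (adjusted p = 0.075), and the Cd36 call without any one of CD206neg replicates 1, 2 and 3 or CD206pos replicate 2 (adjusted p between 0.061 and 0.078). Il10 was at 0.76 ± 0.41 and 2.02 ± 1.19 CPM (adjusted p = 0.54) and Tgfb1 at 2.44 ± 1.59 and 2.55 ± 0.92 CPM (adjusted p = 0.98). None of 19 type I interferon response genes and none of 6 MHC class II presentation genes passed in edgeR's test (camera adjusted p = 0.82 and 0.15), whether adjusted over all genes or over the list alone, with 2 and 1 of them at an unadjusted p under 0.05, 1 and 1 called by DESeq2, and 1 and 0 called by limma-voom. With the litter block camera called the MHC class II list lower (adjusted p = 0.034). For the interferon list the median (0.11) and the mean (0.01) lay above 0 and the list test pointed down. Of 19 pattern recognition receptor genes 2 rose and 17 did not pass (median 0.62, 6 higher and 2 lower when adjusted over the list alone). Tlr7, a receptor for single-stranded RNA, rose 2.66-fold, and Tlr1, 2.38-fold, was no longer called without CD206neg replicate 2 or 3 or CD206pos replicate 2 or 3 (adjusted p between 0.055 and 0.10). Camera called the list higher (adjusted p = 0.010), fry did not (adjusted p = 0.059), and with an estimated correlation the adjusted p was 0.37.

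Lists of scavenger receptors, complement, lysosome and iron handling were called higher in CD206pos. Of 16 scavenger and endocytic receptor genes 7 rose and 9 did not pass (median 1.02, 9 higher when adjusted over the list alone), including the scavenger receptor gene Msr1, which rose 4.22-fold. Of 13 complement genes 5 rose and 8 did not pass (median 0.51, 5 higher and 2 lower when adjusted over the list alone). The C1q subunit genes C1qa, C1qb and C1qc rose 5.35-fold, 3.12-fold and 3.80-fold, C1qb from 1031 ± 108 to 3212 ± 244 CPM, and the complement C5a receptor gene C5ar1 rose 4.54-fold. Of 27 lysosome genes 7 rose and 20 did not pass (median 0.57, 17 higher when adjusted over the list alone), among them the cathepsin B gene Ctsb, 3.57-fold from 1946 ± 311 to 6940 ± 1584 CPM, and the progranulin gene Grn, 3.02-fold. Of 16 genes of iron and haem handling 7 rose and 9 did not pass (median 0.88, 11 higher when adjusted over the list alone). The iron exporter gene Slc40a1 rose from a mean of 58.0 CPM to 607 CPM (log2 fold change 3.39 ± 0.35, SE), the haem oxygenase gene Hmox1 rose 3.02-fold, the biliverdin reductase gene Blvrb 4.85-fold and the ferritin heavy chain gene Fth1 1.93-fold. Camera called these 4 lists higher (adjusted p = 8.9e-07, 0.0074, 2.4e-07 and 1.1e-09). With an estimated correlation the adjusted p values were 0.11, 0.38, 0.29 and 0.11, and without litter 3 the complement call was lost (adjusted p = 0.086).

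Of 17 matrix remodelling genes 5 rose, 1 fell and 11 did not pass (median 0.64, 7 higher and 2 lower when adjusted over the list alone). The metalloproteinase inhibitor gene Timp2 rose 7.90-fold and the protease gene Adamts1 rose 4.30-fold. The gene that fell, Mmp8, encodes the collagenase of neutrophil granules and was at 15.4 ± 8.15 CPM in CD206neg and 0.15 ± 0.26 CPM in CD206pos, a call lost with limma-voom (adjusted p = 0.10) and without CD206neg replicate 2 (adjusted p = 0.095) or CD206neg replicate 3 (adjusted p = 0.072). The list's camera call (adjusted p = 0.024) was lost without CD206neg replicate 2 (adjusted p = 0.061) and without CD206pos replicate 3 (adjusted p = 0.11), and with an estimated correlation its adjusted p was 0.28. Of 23 growth factor and niche signal genes 2 rose, 3 fell and 18 did not pass, and the counts were equal when adjusted over the list alone. The bone morphogenetic protein gene Bmp2 rose 4.70-fold, from 5.86 ± 0.93 to 27.5 ± 8.73 CPM, a call lost without CD206neg replicate 2 (adjusted p = 0.059) or CD206pos replicate 2 (adjusted p = 0.064). The insulin-like growth factor genes moved in opposite directions: Igf1 rose 5.68-fold and Igf2 was 13.4-fold lower in CD206pos, at 5.98 ± 6.55 against 79.9 ± 25.6 CPM. The Igf1 call was lost without each library except CD206neg replicate 3 (adjusted p between 0.052 and 0.16) and the Igf2 call without each except CD206pos replicate 3 (adjusted p between 0.051 and 0.11). For this list the median (0.06) and camera (adjusted p = 0.82) pointed up, and the mean (-0.54) and fry (adjusted p = 0.87) pointed down.

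Markers of other cells that a GFP gate could hold were called higher in CD206neg by camera for 7 of 12 lists. Of 17 genes of haematopoietic stem and progenitor cells 12 fell in CD206pos and 5 did not pass (median -4.38, 14 lower when adjusted over the list alone). Cd34, an adhesion molecule of progenitors and endothelium, was 15.3-fold lower, at 38.1 ± 17.2 against 584 ± 134 CPM, Mycn was 62.2-fold lower, and Hoxa7 had no read in CD206pos and was at least 140-fold lower. Of 10 neutrophil and granule genes 8 fell and 2 did not pass (median -5.79, 10 lower when adjusted over the list alone). The myeloperoxidase gene Mpo was 106-fold lower, at 18.1 ± 13.2 against 1917 ± 396 CPM, the proteinase 3 gene Prtn3 was at 26.7 ± 17.3 against 347 ± 29.1 CPM, and the chemokine receptor gene Cxcr2 was 4.83-fold lower. Of 14 monocyte genes 6 fell and 8 did not pass (median -1.14, 6 lower when adjusted over the list alone), among them the haptoglobin gene Hp, 32.8-fold lower at 8.71 ± 5.48 against 286 ± 41.8 CPM. Of 3 mast cell and basophil genes 2 fell (median -7.60, or -6.71 with genes without a read at their bound, and 2 lower when adjusted over the list alone), among them the histidine decarboxylase gene Hdc, 204-fold lower, a call lost with limma-voom (adjusted p = 0.12). Of 7 megakaryocyte and platelet genes 2 fell (median -4.32, 5 lower when adjusted over the list alone), and of 15 endothelial genes 3 fell, among them the receptor genes Flt1, 9.23-fold lower, and Tie1, 4.88-fold lower (median -2.39, 9 lower when adjusted over the list alone). Of 5 lymphoid genes 1 fell (median -4.33, 3 lower when adjusted over the list alone), the interleukin 7 receptor gene Il7r, whose call was lost with the litter block (adjusted p = 0.085) and without any one of the 6 libraries (adjusted p between 0.050 and 0.12). Part of some lists lay outside the test: 10 of 18 granule, 3 of 11 mast cell and basophil, 7 of 14 megakaryocyte and 5 of 14 lymphoid genes were tested. The others had too few reads for the filter, so these counts and medians do not speak for the full lists. Camera called these 7 lists lower, with adjusted p between 3.1e-16 and 0.0020. With an estimated correlation their adjusted p values lay between 0.056 and 0.16.

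As CPM of library totals, the summed level of the granule markers was 2778 ± 620 in CD206neg and 142 ± 27.7 in CD206pos, and that of the progenitor markers 1007 ± 201 and 85.9 ± 29.4. Monocyte markers summed to 799 ± 121 and 173 ± 36.2 CPM, endothelial markers to 372 ± 98.8 and 121 ± 20.2 CPM, and megakaryocyte markers to 117 ± 26.9 and 12.3 ± 5.34 CPM. Lymphoid markers, although called lower by camera, summed to 109 ± 12.6 and 97.8 ± 23.2 CPM with overlapping groups, and mast cell and basophil markers to 57.3 ± 30.3 and 6.62 ± 2.78 CPM. Erythroid markers summed to 10.4 ± 0.86 CPM in CD206neg and 14.6 ± 1.99 CPM in CD206pos. The direction of that sum rested on the erythropoietin receptor gene Epor, named after its value was seen, without which it was 9.38 ± 1.93 and 4.23 ± 1.04 CPM. Of 6 tested erythroid genes 1 fell, the transcription factor gene Gata1, and 5 did not pass (camera adjusted p = 0.30, fry adjusted p = 0.044, 1 higher and 2 lower when adjusted over the list alone). Gata1 was at 4.54 CPM (TMM-scaled) in CD206neg and without a read in CD206pos, a large part of the CD206neg sum left without Epor. The Gata1 call was lost with the litter block (adjusted p = 0.056), with limma-voom (adjusted p = 0.058) and without CD206neg replicate 1, CD206neg replicate 2 or CD206pos replicate 2 (adjusted p between 0.060 and 0.12). Mesenchyme markers summed to 140 CPM in CD206neg and 83.5 CPM in CD206pos in litter 3, against 8.34 to 14.9 CPM in the other 4 libraries. None of 8 mesenchyme, 4 mesonephric and 3 neural marker genes passed in edgeR's test, whether adjusted over all genes or over the list alone (camera adjusted p = 0.89, 0.40 and 0.59). At an unadjusted p under 0.05 there were 0, 1 and 0, DESeq2 called 0, 1 and 0, and limma-voom called none. Of 9 dendritic cell genes 1 fell, Flt3, a receptor that is also in the progenitor list, and 8 did not pass (camera adjusted p = 0.64, 1 higher and 1 lower when adjusted over the list alone). The Flt3 call was lost without CD206neg replicate 1, CD206neg replicate 2 or CD206pos replicate 2 (adjusted p between 0.066 and 0.087). The median of this list (0.03) and camera pointed up and its mean (-0.19) down. Its sum over library totals was higher in each CD206neg library than in each CD206pos library (577 ± 49.8 and 492 ± 28.6 CPM). These sums are not scaled by TMM, and a gap this small may not outlast that scaling.

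**Figure D3:**
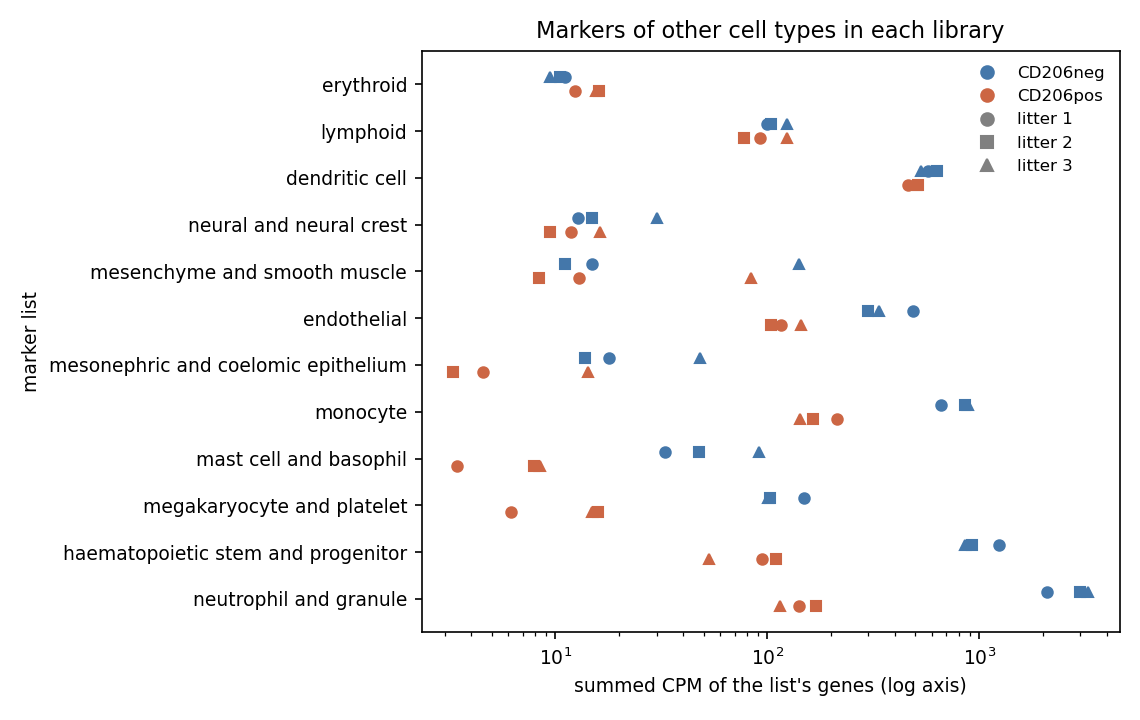
Summed CPM of the genes of 12 marker lists of other cell types, on a log axis, with 1 point per library, colour for the population and marker shape for the litter. Granule markers lie at 2080 to 3261 CPM in the CD206neg libraries and 115 to 170.0 CPM in the CD206pos libraries, and mesenchyme markers stand apart in both libraries of litter 3.

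Few genes of the cell cycle and of glycolysis passed the threshold. The replication markers summed to 9033 ± 481 CPM of library totals in CD206neg and 7594 ± 224 in CD206pos. The mitosis markers summed to 6137 ± 156 and 5541 ± 300. Without TMM scaling, both sums were higher in each CD206neg library than in each CD206pos library. TMM factors were 1.01 to 1.05 for CD206neg and 0.96 to 0.98 for CD206pos libraries. That scaling narrows both gaps, and the separation of the mitosis sums in particular may not outlast it. Of 20 replication genes 1 fell, the replication helicase component gene Cdc45, 1.65-fold lower at 97.6 ± 15.7 against 161 ± 5.60 CPM. Of 21 mitosis genes none passed in edgeR's test. Both lists had the same counts when adjusted over the list alone (camera adjusted p = 0.18 and 0.67). At an unadjusted p under 0.05, 6 replication genes were lower and none was higher. No mitosis gene was at an unadjusted p under 0.05 or called by DESeq2 or limma-voom. The Cdc45 call was lost without each library except CD206pos replicate 1 (adjusted p between 0.10 and 0.16). Of 18 glycolysis genes the hexokinase gene Hk3 rose 2.69-fold and Hk1 was 2.07-fold lower (camera adjusted p = 0.89, with the same counts when adjusted over the list alone). The Hk1 call was lost with the litter block (adjusted p = 0.060), with RLE scaling (adjusted p = 0.050) and without any one of the 6 libraries (adjusted p between 0.058 and 0.19), and the Hk3 call with upper-quartile scaling or library totals (adjusted p = 0.051 and 0.060) and without each library except CD206pos replicate 1 (adjusted p between 0.076 and 0.16). Of 20 immediate early and dissociation response genes 6 rose in CD206pos and 14 did not pass (median 0.65, 10 higher when adjusted over the list alone). The early response transcription factor gene Egr1 rose 2.85-fold, from 290 ± 35.0 to 828 ± 20.8 CPM, and Zfp36, whose product destabilises inflammatory mRNAs, rose 1.97-fold. Camera (adjusted p = 4.0e-05) and fry (adjusted p = 0.0041) called the list higher, with an adjusted p of 0.095 with an estimated correlation.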

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

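All alternatives were planned before the data were examined, and the cause of a change was not tested. Where fewer libraries entered the fit, lower power was not separated from the effect of the library or litter left out. The 617 calls (376 higher, 241 lower in CD206pos) stayed within 1.5 times under every scaling, filter, thinning, gene removal and litter block, at 557 to 722 genes. The litter block gave 703 genes, 436 higher and 267 lower, of which 330 and 179 were among the original calls. Limma-voom gave 814 and DESeq2 1210 (660 higher, 550 lower). No call of the original 617 turned its sign under any alternative. Leaving out 1 library gave 190 to 561 genes (123 to 355 higher, 67 to 206 lower), with the fewest without CD206neg replicate 2 and the most without CD206pos replicate 1. With 4 libraries, 307 genes (214 higher, 93 lower) were called without litter 1, 3 (2 higher, 1 lower) without litter 2, with 1401 at an unadjusted p under 0.05, and 153 (73 higher, 80 lower) without litter 3. The Mrc1 log2 fold change was 3.84 without litter 1, 4.22 without litter 3 and 4.15 without litter 2, where its adjusted p was 0.075. Of the 89 called named genes, 53 stayed called in all 6 fits that left out 1 library. The litter block ended 8 of the 89 calls (Ccr2, Cxcl2, Folr2, Gata1, Hk1, Il7r, Sox17 and Vegfc), added that of Cx3cr1 and changed no other call of a named gene. Camera called 11 lists higher and 7 lower. With an estimated correlation it called 0 higher and 0 lower, with a smallest adjusted p of 0.056 and 11 lists at an unadjusted p under 0.05, and fry called 8 and 8. The litter block left the 18 list calls in place and called 8 lists lower, the added one being MHC class II antigen presentation (adjusted p = 0.034). Among the 18 list calls, matrix remodelling was lost without CD206neg replicate 2, CD206pos replicate 3, litter 2 or litter 3 (list test: matrix remodelling, adjusted p = 0.061, 0.11, 0.076 and 0.069), and pattern recognition receptors and complement were lost without litter 3 (list test: pattern recognition receptors, adjusted p = 0.053; list test: complement, adjusted p = 0.086). Sign changes concerned genes without a call: the Tgfb1 log2 fold change (0.06) was -0.029 with library totals, -0.53 without litter 3, and -0.28 to 0.74 when 1 library was left out, and the Il6 log2 fold change (0.37) was -0.33 without litter 1 and -0.043 to 1.16 when 1 library was left out. List counts were not recomputed for DESeq2 and the fit without robust estimation, since the list tests use neither. The floor of 3 reads used here stands for 0.16 to 0.18 CPM per library and is not a detection limit. Over simulated genes of all levels, edgeR recovered 30% of 2-fold changes.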

Other observations

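The tests of gene families and all tests below other than the regroupings of libraries were chosen after the results were seen. Genes were grouped by the letters of their symbols before the first digit, and 296 families with at least 6 tested members were compared with all tested genes by a one-sided hypergeometric test. Of 9 tested Ccl chemokine genes, 7 were higher in CD206pos (Ccl2, Ccl4, Ccl6, Ccl7, Ccl9, Ccl12 and Ccl24, adjusted p = 1.9e-07), 6 with upper-quartile scaling or library totals, where Ccl24 was not called. Ccl9 rose from 61.8 to 201 CPM and Ccl6 from 43.8 to 106 CPM. Of 7 tested Ms4a genes, which encode membrane proteins with 4 membrane spans, 4 were higher (Ms4a4a, Ms4a6b, Ms4a6c and Ms4a6d, adjusted p = 0.0037) and 1 was lower (Ms4a3). Ms4a6b rose from 140 to 624 CPM and Ms4a6d from 63.3 to 284 CPM, and since reads shared by paralogs are not counted these levels are uncertain. Of 28 sorting nexin (Snx) genes, whose products act in endosomal transport, 6 were higher (Snx2, Snx3, Snx6, Snx8, Snx24 and Snx30, adjusted p = 0.014). With library totals Snx30 was not called and 5 were higher, and the hypergeometric adjusted p of the family was 0.029. Snx6 was at 402 and 1086 CPM and Snx2 at 973 and 2029 CPM. No family was enriched among the lower genes, with a smallest adjusted p of 0.23. Genes of a family are not independent of each other, and the members named here were chosen after their values were seen, except Ccl2 and Ccl4, which were fixed by name beforehand. Ccl7, Ccl12 and Ms4a3 were taken by the rule for named genes because of the size of their change in these data.

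Of the tested progenitor, granule and megakaryocyte genes, 12 of 17, 8 of 10 and 2 of 7 were called higher in CD206neg, Kit without a read in CD206pos. With an estimated correlation camera called none of the 3 lists (adjusted p = 0.056). Depth is argued against by the library totals: the largest was 1.09 times the smallest and the mean total of CD206neg was 0.98 times that of CD206pos, while the upper quartile of the log2 fold changes of the 34 tested progenitor, granule and megakaryocyte genes was -3.32. Carry-over of GFP-negative AGM cells is left open, since the marker sums do not decide. The erythroid sum was lower in CD206neg (ratio of means 0.71), but without the single gene Epor it was higher in each CD206neg library than in each CD206pos library (ratio 2.22). That second ratio rested in large part on Gata1, at 4.54 CPM (TMM-scaled) in CD206neg and without a read in CD206pos. With Gata1 left out and Epor kept, the ratio was 0.39. Endothelial markers (372 and 121 CPM) and mesonephric markers (26.6 and 7.34 CPM) summed higher in CD206neg as well, the granule markers at 2778 and 142 CPM. Mesenchyme markers summed to 140 and 83.5 CPM in litter 3 and to 8.34 to 14.9 CPM in the other 4 libraries, which argues for neither side. The globin gene Hbb-y was at 0.80 CPM in CD206neg and 0.99 CPM in CD206pos, too few reads to compare the populations. Hbb-y and Epor were named after their values were seen. All erythroid markers, globins included, summed to only 10.4 CPM in CD206neg and 14.6 CPM in CD206pos, so little red-cell RNA was counted in either population. This covers red cells only and no other GFP-negative cells. It stays open whether GFP-positive progenitors and granulocyte precursors lie in the CD206neg gate, since the Csf1r promoter may be active in them, or whether GFP-negative cells of these or other lineages were carried over.

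CD206-high resident macrophage genes were higher in CD206pos by a median log2 fold change of 2.83. If other cells in CD206neg had only diluted the RNA of like macrophages, macrophage-restricted genes should differ by about 1 factor. The 9 reference genes Adgre1, Fcgr1, Mertk, C1qa, C1qb, C1qc, Aif1, Trem2 and Cx3cr1 had a median of 1.28 (quartiles 0.74 and 1.87), 1.54 below that of the list, whose lower quartile was 2.32 (two-sided exact permutation test over genes, p = 0.033). With any 1 reference gene left out, that p lay between 0.024 and 0.061, and it was 0.061 without Fcgr1, Mertk, Trem2 or Cx3cr1. The upper quartile of the reference genes then lay between 1.70 and 1.89, below the lower quartile of the list. The permutation takes genes as independent units, although all come from the same 6 libraries and C1qa, C1qb and C1qc lie side by side on chromosome 4. Of the 15 list genes 11 lay above the highest reference gene (2.42 ± 0.19), 6 of them with intervals of 2 standard errors that did not meet, and the lowest reference gene was at 0.65 ± 0.15. These values argue against 1 common factor as the whole cause, although the reference genes were chosen after the results were seen and other cells may express some of them. A further reference gene, not reported here, was left out after the first result was seen, so the p values apply to the set without it. Dilution may hold for part of the difference, and a macrophage state that goes with surface CD206 is a hypothesis that these data cannot separate from a mixture of several macrophage types.

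The 21 tested pro-inflammatory genes had a median log2 fold change of 0.80, with 7 higher in CD206pos, 1 lower and 13 not past the test. The list was not called by camera with an estimated correlation (adjusted p = 0.056). The median of the same 9 reference genes was 1.28 (difference -0.48, exact permutation p = 0.27). The 7 called genes that rose lay between 1.10 and 2.62 against a range of 0.65 ± 0.15 to 2.42 ± 0.19 for the reference genes. Only Ccl2 (2.62 ± 0.27) lay above that range, and its interval of 2 standard errors met that of the highest reference gene. The reference genes differ among themselves and so give no single dilution factor to set these genes against. Dilution of macrophage RNA in CD206neg and a higher inflammatory expression per macrophage therefore cannot be told apart here for the genes that rose. The 1 called gene that fell, Il12a, has no read in CD206pos. Expression by other cells in CD206neg would give the same pattern, so this gene does not decide for or against dilution. A response to dissociation could also contribute: the 15 immediate early genes had a median of 0.82, while the 5 heat shock genes had a median of -0.13 and none of them passed. Both populations went through the same digestion and no undigested cells were analysed here, which keeps this explanation open.

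The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 617 genes (376 higher, 241 lower), as 1 of the 10 splits. The highest other count was 0 for all 3 numbers in edgeR, with 152 to 1073 genes at an unadjusted p under 0.05. Each other split puts libraries of both populations on each side, so a population difference adds to the spread within sides. A count of 0 there is therefore no measure of chance. For gene lists the real split gave 11 higher, with 10 the highest other count in one direction, and 7 lists lower. As a mirrored split swaps the directions, both numbers were set against the larger direction of each other split, and by that count 3 of the 10 splits reached 7, the real one and those with 10 and 9 lists. In the smaller direction no other split gave more than 4. The split that gave 10 lists set both libraries of litter 1 and CD206neg replicate 2 against the rest. Among the 4 splits that part all 3 litters, the other 3 gave at most 4 lists in one direction.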
